A study of Mus musculus with 8 samples.

How the data were processed

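Total RNA of tumour tissue was extracted with Trizol, depleted of ribosomal RNA and made into directional libraries, per the labels' protocols. The labels describe the tissue as sorted and name no gate or marker. The authors deposited 1 table of raw read counts per gene for 8 samples, with 57132 genes named by Ensembl identifier and symbol, per the file headers. Cutadapt 4.6, STAR 2.7.11b and the mouse genome GRCm39 are named per the submitters' processing notes, which give no role or order here. The counting tool, its strand setting and the gene annotation are not given in the sources used here, so genes that share reads with an overlapping, antisense or near-identical neighbour are uncertain. Between 77.9% and 83.8% of the gene counts from 1 to 20 were even numbers, the pattern left when the reads of a pair are counted one by one, and an alternative with all counts divided by 2 and rounded up was run for that reason. No batch, date or lane is given in the labels. The 484 rows with no symbol held 0.0128% to 0.0176% of the reads of a library and were kept under their identifiers.

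Counts as deposited were tested with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr (16588 genes, with 0.0694% to 0.109% of reads removed), libraries were scaled by trimmed means (TMM), and PDT minus PBS was fitted with edgeR's quasi-likelihood test and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. The biological coefficient of variation was 0.392. CPM values are counts-per-million of the TMM-scaled library, and group values are mean ± SD over 4 libraries. Replicates were compared by a chi-square test of their counts, and the 28 pairs differed by 70.9 to 223 chi-square units per degree of freedom, so no library was a copy of another.

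Gene lists, 35 in all with 540 entries, were written from textbook knowledge before the data were examined, as were the tests of genes, lists and scores between the groups, the rule for named genes and all alternatives except a pair named below. Some tests of explanations were chosen later and are named with their results. They cover cytosolic DNA sensing, interferon-stimulated genes, antigen presentation, immune cell types, chemokines, checkpoints, fibroblasts, matrix and its enzymes, TGF-beta signalling, vessels, tumour epithelium, stress and death pathways, cell cycle, ribosomal and mitochondrial genes, and tissues that could be dissected along with a tumour. A symbol on several identifiers was taken at the one with most reads, and 1 entry, Lor, was not matched. Lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01. Each list also had a score per library, the mean log2 CPM of its members with a prior count of 2, tested between groups by a two-sided exact permutation over all 70 assignments, whose smallest p is 0.0286. The genes named were the 6 with the largest rise and the 6 with the largest fall among those with adjusted p under 0.05, a mean of at least 1 CPM and groups that did not overlap, leaving out predicted, mitochondrial and ribosomal RNA genes by symbol. To these were added the 3 members with the smallest p of each list past the camera threshold, the 1 member with the smallest p of each other list, and always Cgas, Sting1, Tbk1, Irf3, Ifnb1, Cxcl10, Ccl5 and Isg15. A gene that this rule takes is not reported here.

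The fit was tested on simulated data in which 200 genes were changed, drawn from the means and library sizes of these samples for the PDT minus PBS comparison with 15943 genes kept. It recovered 5.45% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 72.7% of those changed 4-fold, with 6 false calls among 89. A list planted with a change was called, and so was 1 of the 34 others. Genes were drawn independently of each other in this simulation. In the data the inter-gene correlation was estimated at 0.43 for the macrophage list and 0.84 for the erythroid list. The share of unchanged lists called therefore does not carry over to the data.

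Alternatives were other scalings (RLE and upper quartile), no count filter, a filter of 1 CPM in 4 samples, the replicate number as a block, genes of other tissues and mitochondrial genes removed, each library left out in turn, DESeq2 1.42.0, limma-voom with sample quality weights, a 2-fold minimum with adjusted or unadjusted p, camera with an estimated correlation, and fry. A correction for GC content and transcript length and the counts divided by 2 were added after the data were seen. The correction fitted natural splines with 4 degrees of freedom per library to GC content and log2 transcript length. Lengths and GC came from a GENCODE mouse annotation of the preceding assembly, used by identifier for these alone, and 98.1% of tested genes were matched. No coordinates are given, since an annotation of GRCm39 was not used here.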

Results

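Bulk RNA was sequenced from subcutaneous KPC tumours of mice, KPC being a mouse model of pancreatic cancer. One group of 4 samples came from mice given PBS, a buffered saline. The other group of 4 came from mice given Ce6@D4-EV followed by light, called PDT (photodynamic therapy) here. Ce6 is chlorin e6, a photosensitiser that makes reactive oxygen species when lit, and D4-EV is its carrier as named by the submitters. The single comparison, PDT minus PBS, asks which genes differ between treated and control tumours, and whether immune, stromal and cytosolic DNA sensing genes are among them. No arm with light alone or with the unlit carrier was analysed here. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples. Summed gene counts were 35742024, 40337306, 37286426 and 35876472 in PBS 1 to PBS 4, and 48804713, 39026840, 42973592 and 41763647 in PDT 1 to PDT 4. A gene with 0 reads in a library could still hold up to 3 reads by chance, which corresponds to at most 0.0872 counts-per-million (CPM) of the scaled library, in PBS 4. These floors cover counting error only, and are too low where both reads of a pair were counted.

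The libraries separated by treatment on the first principal component, which held 25.0% of the variance. All 4 PDT libraries lay above all 4 PBS libraries on it (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow, and 0.114 after adjustment over 4 components). PBS 1 lay far from the rest at −111.5, against −8.53 to 4.32 for the other PBS libraries and 16.1 to 37.2 for PDT. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.919 to 0.938 within PBS, 0.949 to 0.971 within PDT and 0.919 to 0.9499 between groups. Reads from mitochondrial genes made up 2.62 ± 0.383% (SD, n = 4) of the total in PBS and 1.91 ± 0.344% in PDT (exact permutation p = 0.0571, 0.171 after adjustment over 8 library measures). Genes with at least 1 read numbered 18832 ± 954 in PBS and 20667 ± 1219 in PDT (SD, n = 4, exact permutation p = 0.0857). The 18S ribosomal RNA gene Rn18s took 1.34% of reads in PDT 4 and 0.275% to 0.363% in the other PDT libraries.

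Of the genes named by rule for their size of change, 6 rose and 6 fell in PDT. The largest rise was that of Gpnmb (ENSMUSG00000029816), a transmembrane glycoprotein of macrophages and lysosomes. It rose 7.35-fold, from 8.45 ± 2.34 to 62.1 ± 28.6 CPM (SD, n = 4), a log2 change of 2.88 ± 0.34 (SE, adjusted p = 0.0202 by edgeR). Lst1 (ENSMUSG00000073412), a leukocyte-specific transcript, rose from 4.77 ± 2.22 to 19.96 ± 5.45 CPM, a log2 change of 2.07 ± 0.33. Pstpip1 (ENSMUSG00000032322), a cytoskeletal adaptor of blood cells, rose by 1.42 ± 0.22 on the log2 scale, from 11.9 ± 3.85 to 31.8 ± 2.50 CPM. The other named rises were C1qtnf2 (ENSMUSG00000046491), a secreted protein of the C1q and TNF family, by 1.75 ± 0.23, AB124611 (ENSMUSG00000057191) by 1.57 ± 0.23, and Tpm2 (ENSMUSG00000028464), the beta-tropomyosin of contractile cells, by 1.52 ± 0.25. Tpm2 was highest in PDT 2, at 343 CPM against 152 to 223 CPM in the other PDT libraries, and PDT 2 also held the highest score of skeletal muscle genes, 7.004. Slc14a1 (ENSMUSG00000059336), a urea transporter, fell from 14.3 ± 5.14 to 3.02 ± 0.848 CPM, a log2 change of −2.24 ± 0.32 (adjusted p = 0.03 by edgeR). Nptx1 (ENSMUSG00000025582), a neuronal pentraxin, fell from 61.5 ± 26.1 to 16.1 ± 2.51 CPM, a log2 change of −1.94 ± 0.27. The remaining named falls were Clca3a1 (ENSMUSG00000056025), related to chloride channel regulators, at −1.92 ± 0.25, the zinc transporter Tmem163 (ENSMUSG00000026347) at −1.62 ± 0.28, the neurturin receptor Gfra2 (ENSMUSG00000022103) at −1.34 ± 0.19 and Klhl1 (ENSMUSG00000022076) at −1.25 ± 0.20. Adjusted p-values of these 12 genes ran from 0.0202 to 0.0497, and in each all 4 values of one group lay above all 4 of the other, as the naming rule required.

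**Figure D1:**
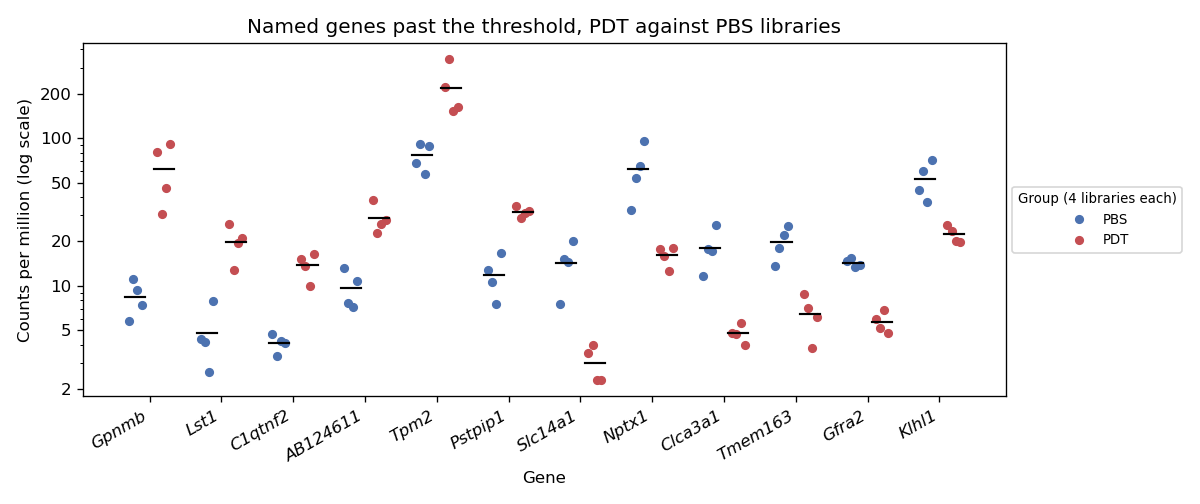
CPM (log axis) of the 12 named genes past the threshold, one point per library, with 4 PBS libraries in blue and 4 PDT libraries in red. Black lines mark group means, for instance 8.45 CPM in PBS and 62.1 CPM in PDT for Gpnmb, and the points of the groups do not overlap in any of these genes, as the naming rule required.

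In all, 39 of 16588 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 27 higher and 12 lower in PDT. At an unadjusted p under 0.05 there were 2737 genes, where 829.4 would be expected with no effect, and 388 genes had an adjusted p under 0.1. All 39 had groups that did not overlap, as did 10.1% of the tested genes, where chance gives 2.86%. The number of genes past the threshold hung on single libraries. It was 10, 4, 0 and 122 without PBS 1, PBS 2, PBS 3 and PBS 4, and 0, 112, 3 and 3 without PDT 1, PDT 2, PDT 3 and PDT 4. Where edgeR left 0 genes, 2349 (without PBS 3) and 2162 (without PDT 1) had an unadjusted p under 0.05. The 12 named genes kept their direction in all 8 of these fits, which the naming rule made all but certain, since it took only genes whose groups did not overlap. Gpnmb, with log2 changes of 2.64 to 3.12, lost its call without PBS 3 and without PDT 1. The other named genes of these 12 lost theirs in 4 (C1qtnf2) to 7 (Tmem163) of the 8 fits. DESeq2's Wald test gave 869 genes (518 higher) and limma-voom 167 (100 higher), which held 39 and 38 of the same genes. A correction for GC content and transcript length left 13 genes, 6 higher and 7 lower and 9 of them shared, and ended the calls of Lst1, AB124611, Tpm2, Pstpip1, Tmem163 and Klhl1 at adjusted p-values of 0.0511 to 0.0855. Their log2 changes after it were 1.89 ± 0.30, 1.297 ± 0.22, 1.35 ± 0.28, 1.23 ± 0.23, −1.68 ± 0.29 and −1.03 ± 0.21 (SE), in that order. Over all alternatives the adjusted p-values of these 6 genes ran from 4.54e-07 to 0.155.

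Markers of macrophages and monocytes, the phagocytes that clear dying cells, were higher in PDT for all 20 measured members, with a median log2 fold change of 0.66. Cd68 (ENSMUSG00000018774), a lysosomal glycoprotein of macrophages, rose from 69.1 ± 11.9 to 124 ± 11.98 CPM (SD, n = 4), a log2 change of 0.85 ± 0.15 (SE, adjusted p = 0.0497 by edgeR). It was the 1 member past the threshold over all genes in edgeR, against 9 in DESeq2 and 3 in limma-voom, and lost its call in edgeR without any one of the 8 libraries and after the GC and length correction, whereas 13 members passed when adjusted over the list alone. Ly6c2, a surface protein of inflammatory monocytes, was at 1.97 ± 1.34 CPM in PBS and 10.9 ± 3.61 CPM in PDT, with a log2 difference of 2.46 ± 0.44 (adjusted p = 0.051 by edgeR). Ms4a7, another macrophage surface gene, differed by 1.11 ± 0.21 (adjusted p = 0.0566). In edgeR Ly6c2 passed without PBS 2 (0.0427) and Ms4a7 without PBS 1 (0.0411). With all 8 libraries DESeq2 called both (adjusted p = 5.31e-06 and 8.93e-05), while limma-voom called Ms4a7 (0.0246) and gave Ly6c2 an adjusted p of 0.0519. The macrophage score, the mean log2 CPM of the list, was 5.90 ± 0.34 in PBS and 6.68 ± 0.21 in PDT (SD, n = 4, exact permutation p = 0.0286, 0.167 after adjustment over 35 lists).

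Neutrophil markers were higher in PDT for all 13 measured members, with a median of 1.14. Csf3r, the receptor for granulocyte colony-stimulating factor, differed by 1.37 ± 0.25 (SE, adjusted p = 0.0515), Clec4d by 1.58 ± 0.36 (adjusted p = 0.0818) and Stfa2l1 by 2.87 ± 0.83 (adjusted p = 0.122). Of the 13, 0 passed over all genes in edgeR, 7 had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. DESeq2 called 3 and limma-voom 1. Csf3r, Clec4d and Stfa2l1 passed in edgeR without PDT 2, at adjusted p-values of 0.0322, 0.0322 and 0.041. The neutrophil score was uneven among treated samples, at 2.22 in PDT 2, inside the PBS range of 1.79 to 2.52, and at 3.42 to 4.34 in the other PDT libraries (exact permutation p = 0.0857).

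Markers of NK and cytotoxic cells had a median log2 fold change of 0.995, with 12 of 13 members higher, and T cell markers one of 1.06, with 13 of 17 higher. Gzma, a granzyme of cytotoxic lymphocytes, had 0 to 20 reads in the PBS libraries and 98 to 278 in the PDT libraries, a log2 difference of 4.203 ± 0.89 (SE, adjusted p = 0.0678 by edgeR). Xcl1, a chemokine of the same cells, had 0 to 8 reads in PBS and 18 to 58 in PDT (adjusted p = 0.195), and Gzmb differed by 1.62 ± 0.90 (adjusted p = 0.408). Among T cell genes, Cd3d, a part of the T cell receptor complex, was at 1.37 ± 0.882 CPM in PBS and 3.60 ± 0.638 CPM in PDT, a log2 difference of 1.39 ± 0.50 (adjusted p = 0.193). Cd8b1 had 0 to 34 reads in PBS and 40 to 126 in PDT (adjusted p = 0.232), and Cd28 differed by 2.21 ± 1.17 (adjusted p = 0.384). The 4 lower T cell members were Tcf7 at −0.27, Trbc1 at −0.34, Trac at −0.18 and Cd6 at −0.34. Their adjusted p-values were 0.488 to 0.918 by edgeR, and they were named after their values were seen. In edgeR 0 members of either list passed over all genes, and 2 of each list had an unadjusted p under 0.05. When adjusted over the list alone, 1 cytotoxic and 0 T cell genes passed, and DESeq2 called 1 and 0 and limma-voom 0 and 0. The scores of all 4 PDT libraries lay above those of all 4 PBS libraries, at −1.04 ± 0.48 in PBS and 0.70 ± 0.16 in PDT for NK and cytotoxic cells and at −0.10 ± 0.74 and 1.09 ± 0.16 for T cells (SD, n = 4, both exact permutation p = 0.0286, 0.167 after adjustment). Requiring 1 CPM in 4 samples took the T cell median to 0.26 and its camera adjusted p to 0.0607, with a range of 0.000101 to 0.601 over all alternatives.

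Camera, which compares a list with all other genes, gave adjusted p-values of 1.04e-13 for macrophages and monocytes, 2.1e-07 for neutrophils, 0.000246 for NK and cytotoxic cells and 0.00921 for T cells, at a preset correlation of 0.01. With an estimated correlation the adjusted p-values were 0.253, 0.364, 0.22 and 0.601. Across the 35 lists, camera called 12, 9 higher and 3 lower, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move one way on balance, called 1 list, NK and cytotoxic cells (adjusted p = 0.0211). Its mixed form, which takes changes in either direction, called 14 of the 35 lists. Among these were p53 targets and apoptosis (adjusted p = 0.000124), endothelium (0.0176) and extracellular matrix (0.0349), which camera did not call. A number of camera calls this large at the preset correlation was not specific to the treatment split, since 20 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave at least 12 lists. That count does not say which lists were called. Exact permutation of the scores gave p = 0.0286 for 6 lists, macrophages, mitochondrially encoded mRNAs, NK and cytotoxic cells, pyroptosis and necroptosis, T cells and pericytes, and 0 passed after adjustment over 35 lists. In the same samples the mean share of mitochondrial reads was lower and the mean number of genes detected higher in PDT, with the p-values given above.

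**Figure D2:**
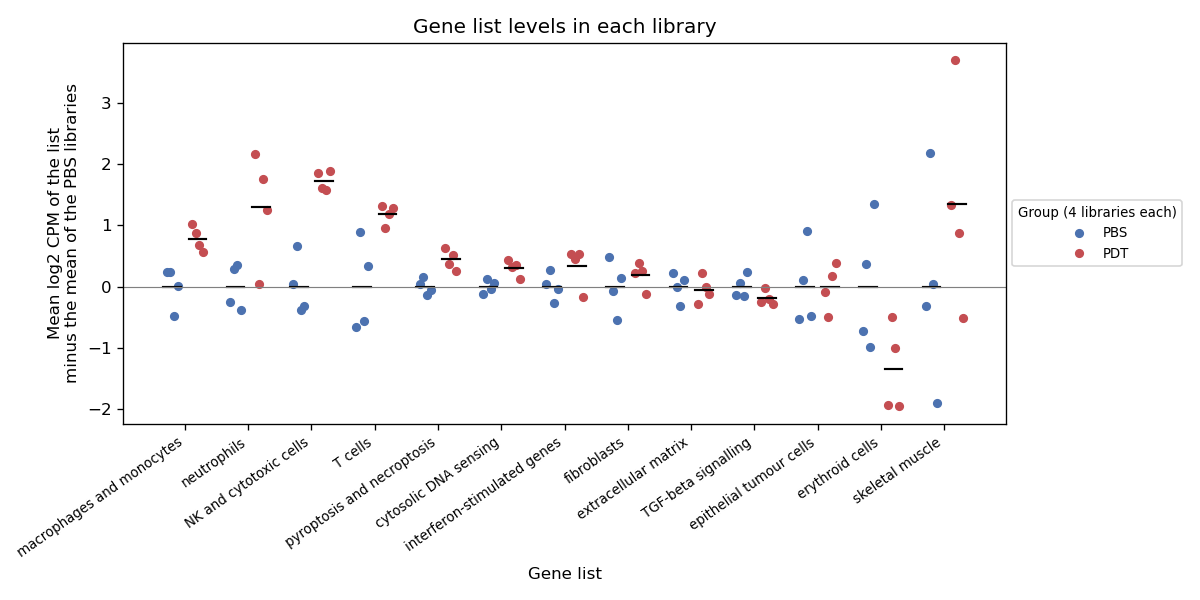
Mean log2 CPM of 13 gene lists in each library, shown as the difference from the mean of the 4 PBS libraries, with PBS in blue, PDT in red and group means as black lines. The PDT points of the macrophage, NK and T cell lists all lie above the PBS points, while the skeletal muscle scores range from 1.38 to 5.49 in PBS and from 2.78 to 7.004 in PDT before that mean is subtracted.

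Components of cytosolic DNA sensing, the pathway named in the study's design, were on the whole slightly higher in PDT. Of 28 measured members 19 were higher, with a median log2 fold change of 0.19, and 0 passed the threshold in edgeR, 5 in DESeq2 and 0 in limma-voom. Macrophage and neutrophil markers, with medians of 0.66 and 1.14, were higher in the same libraries. Whether the difference in this list follows from them was not tested. Cgas (ENSMUSG00000032344), the sensor of cytosolic DNA, was at 3.31 ± 1.77 CPM in PBS and 4.67 ± 1.17 CPM in PDT (SD, n = 4), a log2 difference of 0.50 ± 0.43 (SE, adjusted p = 0.625 by edgeR). Sting1 (ENSMUSG00000024349), its adaptor, was at 36.7 ± 3.06 and 41.3 ± 1.36 CPM, with no overlap and a log2 difference of 0.17 ± 0.12 (adjusted p = 0.516). The kinase Tbk1 (ENSMUSG00000020115) differed by 0.15 ± 0.12 (adjusted p = 0.59) and the transcription factor Irf3 (ENSMUSG00000003184) by 0.23 ± 0.18 (adjusted p = 0.583), or by −0.02 after the GC and length correction. With 1 library left out, the log2 difference of Cgas ran from 0.22 to 0.86 and that of Irf3 from 0.08 to 0.36. All of these values are transcript levels, and the pathway's activation by phosphorylation was not measured. The members with the smallest p were Pycard, the inflammasome adaptor, with a log2 difference of 0.76 ± 0.20 (adjusted p = 0.1), the kinase Ikbke with 0.75 ± 0.21 (adjusted p = 0.115) and the chemokine Ccl4 with 1.89 ± 0.60 (adjusted p = 0.15). Ccl4 reached 21.4 CPM in PDT 1 against 3.77 to 4.99 CPM in the other PDT libraries, and its log2 difference was 0.96 without PDT 1.

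Downstream genes were mixed. Ifnb1 (ENSMUSG00000048806), which encodes interferon beta, had 0 reads in 7 libraries and 6 reads in PDT 3, and was too low to test. Cxcl10 (ENSMUSG00000034855), an interferon-inducible chemokine, was at 10.004 ± 8.08 CPM in PBS and 9.80 ± 2.47 CPM in PDT (SD, n = 4, adjusted p = 0.982 by edgeR), and the PBS mean rested on PBS 2, at 22.1 CPM. Its log2 difference was −0.03, and it turned to 0.72 without PBS 2 and to 0.15 without PDT 1. Ccl5 (ENSMUSG00000035042) differed by 0.36 ± 0.31 (SE, adjusted p = 0.623). Isg15 (ENSMUSG00000035692), a ubiquitin-like protein induced by interferon, was at 8.43 ± 2.91 CPM in PBS and 18.1 ± 4.43 CPM in PDT, with no overlap and a log2 difference of 1.10 ± 0.29 (adjusted p = 0.102). Of 31 interferon-stimulated genes, 27 were higher in PDT, with a median of 0.28, including Bst2 at 0.91 ± 0.23 (adjusted p = 0.0985) and Oas1a at 0.80 ± 0.24 (adjusted p = 0.135). The score of this list was 4.11 to 4.198 in PDT 1, PDT 2 and PDT 3 and 3.49 in PDT 4, inside the PBS range of 3.39 to 3.93 (exact permutation p = 0.143), and without PDT 4 the median of the list was 0.45.

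In edgeR, 0 genes of either list passed over all genes, and 7 of each list had an unadjusted p under 0.05. When adjusted over the list alone, 0 cytosolic DNA sensing and 5 interferon-stimulated genes passed. DESeq2 called 5 of each list, while limma-voom called 0 of each. Pycard (adjusted p = 0.019), Ikbke (0.0319), Ccl4 (0.0183) and Isg15 were among those DESeq2 called (for Isg15 adjusted p = 0.0118, and 0.0118 to 0.25 over all alternatives), and Cgas, Sting1, Tbk1 and Irf3 were not. Camera gave adjusted p-values of 0.0139 for cytosolic DNA sensing and 0.0018 for interferon-stimulated genes, and with an estimated correlation the adjusted p-values were 0.253 and 0.773. The score of the cytosolic DNA sensing list was 4.69 ± 0.11 in PBS and 4.997 ± 0.13 in PDT (SD, n = 4, exact permutation p = 0.0571, 0.286 after adjustment over 35 lists).

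**Figure D3:**
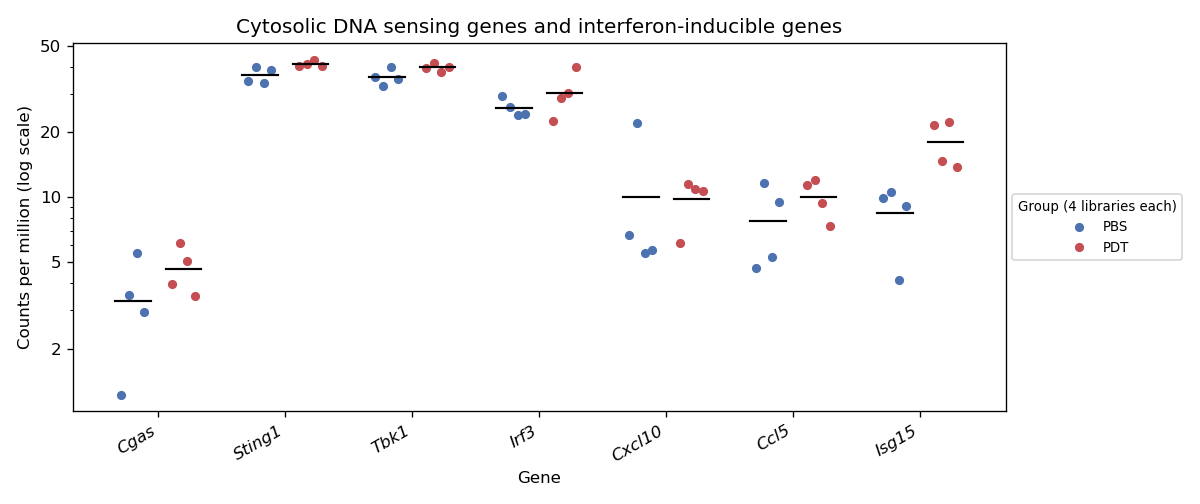
CPM (log axis) of Cgas, Sting1, Tbk1, Irf3, Cxcl10, Ccl5 and Isg15 in each library, PBS in blue and PDT in red, with black lines at group means. Isg15 averages 8.43 CPM in PBS and 18.1 CPM in PDT, and the high PBS point of Cxcl10 is PBS 2 at 22.1 CPM.

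Genes of inflammatory cell death and of inflammatory signalling were higher in PDT on balance. In the pyroptosis and necroptosis list, 11 of 12 members were higher with a median of 0.42, led by Pycard, Zbp1 at 0.90 ± 0.31 (SE, adjusted p = 0.174 by edgeR) and the inflammasome sensor Nlrp3 at 0.76 ± 0.28 (adjusted p = 0.199). This list shares 7 of its 12 members with the cytosolic DNA sensing list, so the pair of lists is not separate evidence. Of 28 chemokines and cytokines, 5 of them also in the cytosolic DNA sensing list, 18 were higher, with a median of 0.34. In the same samples macrophage and neutrophil markers were higher in PDT, with medians of 0.66 and 1.14. Cxcl12 was at 84.0 ± 18.0 CPM in PBS and 157 ± 39.9 CPM in PDT (SD, n = 4), a log2 difference of 0.90 ± 0.20 (adjusted p = 0.08), and the monocyte attractant Ccl2 differed by 1.09 ± 0.27 (adjusted p = 0.0951). Ccl3 differed by 2.96 ± 0.76 (adjusted p = 0.0985), with 1150 reads in PDT 1 and 77 to 367 in the other PDT libraries. Of these lists 0 members passed over all genes in edgeR, and 5 and 9 had an unadjusted p under 0.05. When adjusted over the list alone 1 and 5 passed, DESeq2 called 2 and 5, and limma-voom 0 and 1. Camera adjusted p-values were 0.0017 and 0.00822, and 0.253 and 0.644 with an estimated correlation. The chemokine call was lost without PBS 4 (adjusted p = 0.117, median 0.31) and without PDT 1 (adjusted p = 0.0548, median 0.20), and its median was 0.58 without PBS 2 and 0.54 without PBS 3. Its adjusted p ran from 0.000112 to 0.644 over all alternatives.

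With all 8 libraries, antigen presentation and the other immune lists did not pass camera. MHC class I genes had a median of 0.22 (11 of 14 higher, adjusted p = 0.0594) and class II genes one of −0.24 (8 of 9 lower, adjusted p = 0.193), although Ctss, a protease of the class II pathway, was 0.63 ± 0.17 higher (SE, adjusted p = 0.102 by edgeR). The class I score was 6.87 in PBS 2 and 5.98 to 6.01 in the other PBS libraries, and without PBS 2 the median was 0.61 (adjusted p = 2.11e-07, and up to 0.849 over all alternatives). The class I list also passed without PDT 1 (adjusted p = 0.0493), without PDT 2 (0.0446) and with no count filter (0.0127). The class II list passed in 4 alternatives, without PDT 2 (median −0.52, adjusted p = 0.00281), after the GC and length correction (median −0.47, adjusted p = 0.0172), with the replicate number as a block (0.016) and with no count filter (0.0402), and reached 0.849 in others. Medians were −0.11 for dendritic cells, −0.08 for B and plasma cells, 0.09 for mast cells and −0.06 for immune checkpoints and regulatory T cells. Smallest in p among them were Irf8 at 0.53 ± 0.20 (adjusted p = 0.212), Cd22 at 1.05 ± 0.49 (adjusted p = 0.312), Tpsb2 at 0.66 ± 0.24 (adjusted p = 0.205) and the checkpoint receptor Vsir at 0.71 ± 0.20 (adjusted p = 0.114). Camera placed the B cell and checkpoint lists on the higher side although their medians and means were below 0.

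Stromal genes differed in both directions. The 26 extracellular matrix genes had a median of 0.03 and a mean of −0.05, with 16 higher and 10 lower (camera adjusted p = 0.629). Col4a2, a basement membrane collagen, was at 101 ± 8.88 CPM in PBS and 58.9 ± 8.90 CPM in PDT (SD, n = 4), a log2 difference of −0.78 ± 0.14 (SE, adjusted p = 0.051 by edgeR). Adjusted over the list alone, 3 matrix genes passed, Col4a2, Col4a1 at −0.48 ± 0.13 and Fn1 at −0.75 ± 0.21, the latter pair named after their values were seen. Fibroblast markers had a median of 0.27 (11 of 17 higher, adjusted p = 0.0594), with Pdpn at 0.70 ± 0.18 (adjusted p = 0.0978), and 4 passed over the list alone. The fibroblast median ran from 0.07 without PBS 3 to 0.47 without PBS 1, where the list passed (adjusted p = 0.000101). It also passed without PDT 4 (0.00231), after the GC and length correction (median 0.13, adjusted p = 0.0214), with the block (0.0371) and with no count filter (0.0218), and its adjusted p reached 0.849 in others. In the TGF-beta list 13 of 17 genes were lower, with a median of −0.21, Skil at −0.52 ± 0.12 (adjusted p = 0.0803) and Ltbp1 at −0.85 ± 0.20 (adjusted p = 0.0846), while Tgfbi was higher by 0.51 ± 0.15 (adjusted p = 0.118). Camera gave that list an adjusted p of 0.0136, or 0.689 with an estimated correlation, and 0.171 without PBS 4 (median −0.12), with a range of 0.00138 to 0.689 over all alternatives. Medians were 0.05 for matrix remodelling enzymes, with Mmp9 at 1.78 ± 0.48 (adjusted p = 0.104), 0.27 for endothelium, with Eng at 0.40 ± 0.16 (adjusted p = 0.252), and 0.21 for pericytes, with Des at 1.34 ± 0.67 (adjusted p = 0.352). Des is also a muscle gene, and it was highest, at 441 CPM, in PDT 2, the library with the highest skeletal muscle score. Epithelial tumour cell markers had a median of −0.09 (camera adjusted p = 0.723), with Ocln at −0.57 ± 0.32 (adjusted p = 0.414). In edgeR 0 genes of these 7 lists passed over all genes. At an unadjusted p under 0.05 there were 6 in the matrix list, 6 in the fibroblast list and 6 in the TGF-beta list, of which DESeq2 called 4, 3 and 3 and limma-voom 1, 0 and 2. In the remodelling enzyme, endothelium, pericyte and epithelial lists there were 4, 4, 0 and 0, of which DESeq2 called 1, 0, 0 and 0 and limma-voom 0.

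Markers of tissues beside the tumour varied between libraries. Skeletal muscle genes had a median of 1.33, with 14 of 15 higher, Myh1 at 1.75 ± 0.69 (SE, adjusted p = 0.226 by edgeR), Mylpf at 1.85 ± 0.80 (adjusted p = 0.273) and Tnnt3 at 2.29 ± 1.01 (adjusted p = 0.283). The camera adjusted p was 0.0136, or 0.849 with an estimated correlation, and the call rested on 2 libraries. Without PBS 4 the adjusted p was 0.319, and without PDT 2 the median was −0.29 (adjusted p = 0.728), and over all alternatives the adjusted p ran from 3.45e-18 to 0.849. All 7 erythroid genes were lower in PDT, with a median of −1.43, Alas2 at −1.45 ± 0.44 (adjusted p = 0.139), Hbb-bt at −1.41 ± 0.49 (adjusted p = 0.182) and Hba-a2 at −1.59 ± 0.57 (adjusted p = 0.19). The globin genes share near-identical copies, so their single values are uncertain. The erythroid camera adjusted p was 0.000258, or 0.601 with an estimated correlation, and the exact permutation p of the score was 0.114. PBS 4 held the highest erythroid score, 6.80 against 4.46 to 5.81 in the other PBS libraries, and 314 CPM of Hba-a2 against 39.1 to 123 CPM. Without PBS 4 the erythroid median was −0.71 (adjusted p = 0.0194, with a range of 5.06e-08 to 0.601 over all alternatives). Medians were −0.21 for adipocytes, with Fabp4 at 0.69 ± 0.71 (adjusted p = 0.693, and −0.15 on the log2 scale without PDT 3), −0.61 for keratinocytes, with Sbsn at 0.70 ± 0.39 (adjusted p = 0.412), and −0.05 for Schwann cells. The keratinocyte list passed without PDT 4 (median −1.32, adjusted p = 0.0292, and up to 0.934 over all alternatives), and its median was 0.48 without PBS 3. The adipocyte and Schwann cell lists had means of 0.01 and 0.16, on the other side of 0. Without PBS 2 the adipocyte median was 2.02 (camera adjusted p = 0.000516, and up to 0.852 over all alternatives).

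All 12 tested mitochondrially encoded mRNAs were lower in PDT, with a median of −0.59. mt-Nd6 was at 606 ± 109 CPM in PBS and 330 ± 50.4 CPM in PDT (SD, n = 4), a log2 difference of −0.87 ± 0.16 (SE, adjusted p = 0.0515 by edgeR). It was followed by mt-Nd2 at −0.71 ± 0.18 (adjusted p = 0.101) and mt-Atp6 at −0.90 ± 0.24 (adjusted p = 0.104). In PBS mt-Atp6 was at 14.2 ± 3.08 CPM, against 1763 ± 397 CPM for mt-Nd2, so its value rests on few of the mitochondrial reads. In edgeR 0 passed over all genes, 8 had an unadjusted p under 0.05, and 7 passed when adjusted over the list alone, while DESeq2 called 6 and limma-voom 1. The camera adjusted p was 1.39e-07, or 0.364 with an estimated correlation. The score was 7.75 ± 0.26 in PBS and 7.19 ± 0.25 in PDT (exact permutation p = 0.0286, 0.167 after adjustment over 35 lists). Ribosomal protein genes had a median of 0.08 (camera adjusted p = 0.378), with Rplp1 at 0.37 ± 0.17 (adjusted p = 0.287). The list passed without PBS 4 (median 0.19, adjusted p = 0.042) and without PDT 3 (median 0.15, adjusted p = 0.0352), with up to 0.87 over all alternatives. Immediate early genes had a median of 0.17 (camera adjusted p = 0.67), with Zfp36 at 0.65 ± 0.16 (adjusted p = 0.0906).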

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

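No test in this part was chosen after its result was seen. A library was picked out where it lay far from the other 3 of its group, by the ratio of its gap to the whole range of the group. Of 231 groups of 4 values, 19 were picked out, where about 1 in 20, or 11.6, would be by chance, so many of these are what chance gives.

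PBS 2 accounted for 8 of the 19. It held 25.3 CPM of Oas1a (13.3 to 14.4 in the other PBS libraries), 125 CPM of Tapbp (80.4 to 83.6), 3.96 CPM of Ly6c2 (1.14 to 1.57) and 22.1 CPM of Cxcl10 (5.52 to 6.69). Its MHC class I score was 6.87 against 5.98 to 6.01. Genes of other tissues were high there too, with 177 CPM of the muscle gene Des (34.9 to 48.7), 79.7 CPM of Tnnt3 (4.30 to 9.62) and 151 CPM of the adipocyte gene Fabp4 (16.4 to 24.7).

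Among the other PBS libraries, PBS 3 held 64.0 CPM of Mmp9 (17.4 to 24.9 elsewhere in the group) and PBS 1 held 22.4 CPM of the mast cell gene Tpsb2 (14.7 to 15.98). PBS 1 had the lowest pericyte score, 2.33 (3.25 to 3.39), and the lowest score of immediate early genes, 4.77 (5.14 to 5.22). In PDT 1, Ccl4 was at 21.4 CPM (3.77 to 4.99), Cxcl10 at 6.14 CPM (10.6 to 11.5) and the chemokine score at 4.10 (3.33 to 3.44). PDT 3 held 203 CPM of Fabp4 (41.1 to 55.6) and the 6 reads of Ifnb1, 0.134 CPM against 0 in the other PDT libraries. PDT 4 had an interferon-stimulated gene score of 3.49 (4.11 to 4.198) and 1.34% of reads from Rn18s (0.275% to 0.363%).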

How the results depend on the processing

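The GC and length correction and the counts divided by 2 were chosen after the data were seen. Of 1347 values of 76 named genes under the alternatives, 1166 stayed on their side of the threshold, 79 lost and 102 gained a call. The sign changed in 6 values of 3 genes, Cxcl10, Irf3 and Fabp4, 0 of which passed the threshold in the reported fit or under those alternatives. With 1 library left out, Cxcl12, Mmp9 and mt-Nd6 were among the genes that gained a call. Of 625 values of 35 lists, 569 stayed, 28 lost and 26 gained a call and 2 reversed. List medians changed sign in 42 values of 15 lists, 40 of them past the threshold in neither fit. The number of genes past the threshold, 39, changed with the processing. It was 41 with RLE scaling and 69 with upper-quartile scaling (50 higher), 534 with no count filter and 88 with 1 CPM in 4 samples, 58 without genes of other tissues and mitochondrial genes, 67 with counts divided by 2 and 13 after the GC and length correction. DESeq2 gave 869 and limma-voom 167. Adding a 2-fold minimum left 25, and 418 genes passed an unadjusted p with that minimum. The cause of these differences was not tested, except that the 2-fold minimum can only remove genes. Leaving out 1 library gave 0 (without PBS 3 or PDT 1) to 122 genes (without PBS 4), with 2094 to 2898 genes at an unadjusted p under 0.05 in edgeR. With the replicate number as a block, 182 genes passed, 148 higher, and 35 of the 39 were among them. The data gave no support for a pairing by number, though they cannot exclude one. Same-numbered libraries deviated from their group means with correlations of 0.0385 to 0.0690, and 0 of 4 correlated best with their own number. Camera called 10 to 16 lists when 1 library was left out, 0 with an estimated correlation and fry 1. Calls at list medians of 0.19 (cytosolic DNA sensing), 0.28 (interferon-stimulated genes), 0.66 (macrophages), 1.14 (neutrophils) and 0.995 (NK and cytotoxic cells) were lost with an estimated correlation, and all but the last with fry, where adjusted p-values were 0.07, 0.347, 0.07 and 0.162. The estimated correlation was 0.006 for cytosolic DNA sensing and 0.014 for NK and cytotoxic cells, close to the preset 0.01. Their unadjusted camera p still rose, from 0.00476 to 0.0258 and from 2.81e-05 to 0.00628. This argues against a higher correlation as the cause of the loss for these lists. The setting thus changed more than the correlation, and a loss under it is not by itself a sign of high correlation. It was 0.37 for interferon-stimulated genes, 0.43 for macrophages and 0.48 for neutrophils. The cause of the losses was not tested further. The median of skeletal muscle genes ran from −0.29 (without PDT 2) to 2.73 (without PBS 2) and that of adipocyte genes from −1.21 (without PDT 3) to 2.02 (without PBS 2). The first principal component parted the groups at prior counts of 2 and 0.5 (both exact permutation p = 0.0286). The median log2 fold change of all genes stayed between −0.04 and 0.05 under the scalings, filters, corrections and left-out libraries. Depth limits the T cell and cytotoxic genes most, several of which had 0 reads in a PBS library.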

Other observations

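The test of a lower share of tumour cells, the comparison of the leading lists of each split, the comparison with genes of like expression and the GC and length correction were chosen after the results they bear on were seen. The list of lysosomal genes was written after the rise of Gpnmb was seen and before its own values were, and the other tests in this part were chosen before their results.

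Of the 27 rises, several beyond the genes named by rule are given here as single genes, chosen after their values were seen. Of all 39 genes past the threshold, 1 belonged to an immune list. Ptpn6, a phosphatase of blood cells, had the smallest p of all genes, at 30.1 ± 1.45 CPM in PBS and 65.3 ± 4.97 CPM in PDT (SD, n = 4, log2 change 1.12 ± 0.12 SE, adjusted p = 0.0119 by edgeR). The guanine exchange factor Vav1 rose by 1.31 ± 0.21, the chemokine receptor Cxcr4 by 1.12 ± 0.16, the leukocyte surface protein Cd52 by 0.90 ± 0.15 and the myeloid receptor Sirpa by 0.81 ± 0.13. The lipid-binding protein Fabp5 rose by 1.26 ± 0.19 and the secreted Wnt modulator Sfrp2 by 1.25 ± 0.20. Vav1, Cxcr4, Cd52, Sirpa, Fabp5 and Sfrp2 lost their calls after the GC and length correction, at adjusted p-values of 0.0511 to 0.0848. Their log2 changes after it were 1.17, 1.03, 0.70, 0.74, 1.21 and 1.05, in that order. Gm10180, Rps4l and Erdr1y also passed, but share sequence with related genes or pseudogenes and are uncertain.

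With all 8 libraries, stress pathways did not pass camera. Heat shock genes had a median log2 fold change of −0.09 (8 of 12 lower, adjusted p = 0.0603), with Hspa1b, an inducible chaperone, at −0.87 ± 0.21 (SE, adjusted p = 0.089 by edgeR). Targets of p53 and apoptosis genes had a median of 0.03 (adjusted p = 0.723), with members moving both ways, among them the pore-forming Bax at 0.84 ± 0.19 (adjusted p = 0.0816). The mixed form of fry gave this list an adjusted p of 0.000124. When adjusted over the list alone, 2 members passed as higher and 1 as lower. Oxidative stress genes under NRF2 had a median of 0.10 (adjusted p = 0.224), with the ferritin chain Fth1 at 0.63 ± 0.19 (adjusted p = 0.127). Medians were 0.04 for the unfolded protein response (adjusted p = 0.941), with Dnajb9 at −0.32 ± 0.14 (adjusted p = 0.281), −0.12 for hypoxia and glycolysis (adjusted p = 0.503), with Adm at 0.64 ± 0.27 (adjusted p = 0.259), and 0.12 for the cell cycle (adjusted p = 0.0982), with Plk1 at 0.56 ± 0.19 (adjusted p = 0.174). In edgeR 0 genes of these 6 lists passed over all genes, and in the order given 3, 7, 6, 1, 2 and 5 had an unadjusted p under 0.05. DESeq2 called 2 heat shock, 2 p53 and 1 oxidative stress genes and limma-voom 1 heat shock gene. The heat shock list passed camera in 5 alternatives, after the GC and length correction (median −0.19, adjusted p = 0.0125), with no count filter (0.0145), and without PBS 1 (median −0.17, adjusted p = 0.0161), PBS 3 (0.0214) or PDT 1 (0.0199). The cell cycle list passed without PBS 1 (0.00835) or PDT 1 (median 0.20, adjusted p = 0.00756), the hypoxia list without PBS 1 (0.0463) or PDT 1 (median −0.26, adjusted p = 0.00697) and the oxidative stress list without PDT 2 (median 0.21, adjusted p = 0.0172). Over all alternatives the adjusted p-values of these 4 lists reached 0.773, 0.849, 0.979 and 0.849.

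The number of genes past the threshold was weighed against chance and against a GC or length trend. Chance is an unlikely but not an excluded source of a number this large. Of the 35 splits of the libraries, 1, the real one, gave 39 genes and the highest other gave 1. A share of 1 in 35 is the smallest this test can give, and the number ran from 0 to 122 when 1 library was left out. After the GC and length correction, 0.897 of the 39 genes kept their direction with an adjusted p under 0.1, which argues against such a trend as the whole cause, but 9 kept an adjusted p under 0.05. Of the 30 calls that ended, 26 had a smaller fold change after the correction, with a median ratio of 0.819 over the 30, and 29 a larger unadjusted p: Cd68 went from 0.85 ± 0.15 to 0.60 ± 0.15 (SE) and Lst1 from 2.07 ± 0.33 to 1.89 ± 0.30, whereas Tmem163 went from −1.62 ± 0.28 to −1.68 ± 0.29. A part of the size of many of these changes may follow GC content or length, and a difference in library preparation between the groups stays open, since the labels give no batch.

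The higher levels of macrophage, neutrophil and NK markers were weighed as a set, chosen because these 3 lists led camera among the higher ones. When each split was given its own 3 leading lists, 21 of 35 splits had as large a summed median log2 difference (real 2.80, highest other 5.98), and 20 of 35 gave at least the real 12 camera calls (highest other 18), so chance cannot be excluded for either. The leading lists of another split could be any lists. For the macrophage, neutrophil and NK lists themselves, 1 of 35 splits, the real one, gave a sum this large (highest other 2.14). These lists were picked from the real split, so that count decides nothing. A lower share of tumour cells would raise stromal markers alike, and over all 7 immune cell lists the immune minus stromal score was higher in PDT by 0.52 (exact permutation p = 0.0857), too uncertain to decide. The GC and length correction left 0.955 of the mean of the 3 medians, which argues against a length trend, and genes of like expression had a median of at most 0.0541 of that of a list (10000 random lists), which argues against the lower number of genes detected in PBS acting on genes by their level. Chance, more leukocytes in the treated tumours, or more RNA of these genes per leukocyte may each account for the pattern. The labels call the tissue sorted and name no gate. How it was sorted may also have set the share of leukocytes, and was not tested. A lower share of tumour cells stays open for the macrophage, neutrophil and NK lists, none of which was tested apart against the stromal lists. The score of epithelial tumour cell markers differed by −0.006 between PDT and PBS (exact permutation p = 0.971). Its SD was 0.67 in PBS and 0.38 in PDT, too wide a spread to decide. Bulk counts do not separate the causes named here other than chance.

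Short and GC-rich transcripts were relatively higher in PDT. Across 16274 genes the log2 fold change had a rank correlation of −0.23 with transcript length and 0.26 with GC content, and its median went from 0.15 in the 3258 genes with the shortest transcripts to −0.16 in the 3254 with the longest. Leaving out the 202 genes of the immune lists kept 0.998 of the length correlation, but these were too few of the genes for it to fall, so leukocyte genes as its source stay open. In size, 5 of 35 splits gave a length correlation as large (real 0.23, highest other 0.27) and 9 of 35 a GC correlation as large (real 0.26, highest other 0.31), so chance cannot be excluded. Among PDT libraries the correlation with length ran from −0.34 in PDT 1 to 0.02 in PDT 3, below the PBS range of 0.03 to 0.16. That with GC content ran from −0.12 in PDT 2, inside the PBS range of −0.24 to −0.06, to 0.41 in PDT 4. The length correlation thus parted the groups, while that with GC content did not. RNA integrity or library preparation, of single samples or of a whole group, may underlie the trend, and neither was tested.

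Because Gpnmb marks lipid-laden, lysosome-rich macrophages, a hypothesis was that other genes of that state rose beyond general macrophage markers. A list of 21 lysosomal and lipid-handling genes had a median log2 fold change of 0.40, with 18 higher. Its score was higher in PDT by 0.43 (exact permutation p = 0.0571, two-sided). The same score minus the macrophage score differed by −0.35 between PDT and PBS (exact permutation p = 0.0571, two-sided), the opposite of the prediction, so the data gave no support for such a state beyond macrophage markers in general. Bulk counts do not show which cells the lysosomal RNA came from, so the test cannot exclude such a state either.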
